A study of Mus musculus with 8 samples.

How the data were processed

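Messenger RNA libraries of 8 MB21 samples were analysed, 4 labelled DMSO and 4 labelled with DS-1-38, all taken after 5 days. Per the labels' protocols, cells grew unattached in serum-free medium with B27 supplement, RNA was purified on Qiagen columns, and libraries were made with the Roche Kapa mRNA Hyper Prep kit. The deposited table holds whole-number read counts per gene for each library, together with each gene's length in bases, and the counts had not been normalized by the authors. The submitters' processing notes name STAR 2.7.9a, featureCounts, Subread 2.0.3, R 4.1.0 and edgeR, and the builds GRCm39 and GRCh38.p13, without saying what the human build was for. The strand setting, the treatment of reads that match several places and the annotation release are not given in the sources used here. Genes that overlap another gene, lie antisense to one or have near-identical copies, such as the histone genes, can therefore share reads, and their values are uncertain.

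The table held 55416 gene identifiers, of which 52083 were matched to a symbol in a GENCODE mouse annotation of an earlier build. That annotation served for names and GC content alone, and no coordinates are given because the builds differ. Where several identifiers shared a symbol, the most counted one kept it. The other 68 stayed in the data under the symbol joined to the identifier. In all, 24484 identifiers had no count in any library. The 32 gene lists had 623 entries, of which 619 were matched, 33 of them through an older symbol. Each gene is named by its symbol, for example Gli1 for ENSMUSG00000025407, Hhip for ENSMUSG00000064325, Trib3 for ENSMUSG00000032715 and Eya3 for ENSMUSG00000028886.

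Library totals ran from 17142397 to 28476019 counts. In the model, the common biological coefficient of variation between libraries of a group was 5.53%. Floors given for genes without counts use 3 counts and, since reads without molecular identifiers are not independent molecules, cover counting error only. CPM values, which scale a library's counts to a common total, were adjusted by TMM factors, which ran from 0.9753 to 1.032, except in floors, in shares of a library and for genes under the filter on low counts, where the plain total was used.

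Genes were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test (robust) for DS38 against DMSO with TMM factors and the default filterByExpr minimum of 10 counts, and p-values were adjusted by Benjamini-Hochberg over the 15133 genes kept. The threshold was an adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of the test's F value. Lists with at least 5 tested members, 28 of 32, were tested with limma 3.58.1's camera, which compares a list with the other genes, at a preset correlation of 0.01, two-sided, adjusted over the 28 lists. Camera called 11 of the 28, 4 higher and 7 lower. With an estimated correlation, the calls that held were those of the Hedgehog target and the neuronal differentiation lists. Their estimates were -0.0748 and -0.0278, against 0.333 for the amino acid starvation and Atf4 list and 0.394 for the DNA replication and G1/S list. Which calls held therefore does not follow the size of the change. Each list was also counted member by member, with p-values adjusted over all genes and over the list alone.

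The groups, the model, the threshold, the lists, the rule for named genes and the alternatives, other than those said to be chosen later, were set before the data were examined. The named genes were a set fixed regardless of value that included Gli1, Gli2, Ptch1, Hhip, Mycn, Ccnd1, Atoh1, Eya1, Eya2, Eya3, Eya4 and Six4, the 10 largest rises and 10 largest falls among genes with a mean of at least 4 CPM that passed the threshold with no overlap between the groups, and up to 4 members with the smallest p in each list. Predicted genes and unnamed identifiers were left out of the largest changes. The rule gave 143 tested genes, some of which are not reported here. Wars, Hes1 and Atf4 fall outside it and were named after their values were seen, Wars and Hes1 as the exceptions of their lists.

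The test was first run on simulated counts drawn from the means and totals of these libraries, with 50 genes changed at each of 4 sizes. For DS38 against DMSO, with 14758 simulated genes tested, it recovered 52% of genes changed 1.25-fold, 70% at 1.5-fold, 78% at 2-fold and 98% at 3-fold. Of 161 genes called there, 12 (7.45%) were unchanged ones, a larger share than the threshold aims for. In the data 39.5% of tested genes changed, a far larger share than in the simulation. These recovery rates therefore do not describe the real test.

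The alternatives were DESeq2's size factors in edgeR, library totals alone, the Wald test of DESeq2 1.42.0, limma-voom, no filter beyond removing genes without counts, a filter of 50 counts in 4 libraries, the replicate number as a block, thinning to the smallest total, a fit that was not robust, and leaving out each library in turn. For lists, camera with an estimated correlation and fry were added. A correction for gene length and GC content (lowess, span 0.3) and a fit without both libraries numbered 1 were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.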

Results

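Gene expression was measured by RNA sequencing in MB21 cells, a mouse medulloblastoma line that carries a mutation in Ptch and grows in suspension. Ptch1 encodes the receptor that holds the Hedgehog pathway in check, and its loss drives the Hedgehog subgroup of this cerebellar tumour. The cells were kept for 5 days with 10 uM DS-1-38, which the series describes as derived from benzarone, or with the DMSO vehicle. Each treatment was represented by 4 libraries, called DS38 and DMSO here. Read totals ran from 18878556 to 25582159 counts per DMSO library and from 17142397 to 28476019 counts per DS38 library. Nothing in the labels says that the 4 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

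The first principal component of log2 CPM, the counts of a library scaled to a common total, held 49.2% of the variance and set every DMSO library apart from every DS38 library. On the second, with 14.7%, replicate 1 of each group stood at the same end, at 16 for DMSO and 21.7 for DS38, while DS38 replicate 2 stood at -0.433 and DS38 replicates 3 and 4 at -16 and -14.7. Pearson's correlation over genes was 0.9913 to 0.9949 between libraries of one group and 0.9814 to 0.9893 between groups. Libraries of one group differed by more than counting noise in every pair, so none was treated as a library deposited more than 1 time. The chi-square per degree of freedom was 4.49 to 8.22 between DMSO libraries and 4.25 to 20.5 between DS38 libraries. The high DS38 values, 11.9 to 20.5 for replicates 1 and 2 against 3 and 4, rested on the single identifier ENSMUSG00000119584. Without it, a check made after seeing the data, the values were 3.92 to 6.87 between DMSO libraries, 3.32 to 7.37 between DS38 libraries and at least 15.7 between groups.

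The comparison asks which transcripts differ after 5 days with the compound. Among the largest falls were those of Trib3, Chac1, Nupr1, Slc7a11 and Aldh1l2, all on the list of amino acid starvation and Atf4 target genes. Trib3, a pseudokinase gene induced by amino acid shortage, went from 45.6 ± 5.35 CPM in DMSO to 4.65 ± 0.316 in DS38 (SD, n = 4 each), a 9.72-fold fall. Prph, which encodes the neuronal intermediate filament protein peripherin, showed the largest rise of the named genes, from 7.79 ± 0.956 to 30.6 ± 3.43 CPM, or 3.96-fold. Igfbp5, an insulin-like growth factor binding protein gene, rose 3.02-fold, from 71.0 ± 3.57 to 214 ± 9.24 CPM. Of 15133 genes tested with edgeR's quasi-likelihood test, 5980 changed at a Benjamini-Hochberg adjusted p under 0.05, of which 2840 rose and 3140 fell. At least 2-fold changes made up 355 of these, 241 of them rises and 114 falls. These counts moved with the filter on low counts, to 530 genes raised at least 2-fold without one and, under a stricter one, to 58 genes raised at least 2-fold against 63 genes lowered at least 2-fold, which turned the balance.

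The 10 largest rises and 10 largest falls were sought only among genes with a mean of at least 4 CPM and no overlap between the groups. Besides Prph and Igfbp5, these rises belonged to Myh8, a myosin heavy chain gene (log2 fold change 1.69), and Chrnb4, a nicotinic acetylcholine receptor subunit gene (1.62). The others were the plasma membrane calcium pump gene Atp2b4 (1.46), the carbonic anhydrase gene Car3 (1.44), Rassf4 (1.32), Lmo7 (1.253), Akap12 (1.249) and the homeobox gene Prrx1 (1.24). Less expressed genes could rise more than most of these, as Col1a1 did (log2 fold change 1.81, at 0.233 and 0.798 CPM). The 10 largest falls after Trib3 were those of Trim66 (log2 fold change -3.26), the glutathione-degrading enzyme gene Chac1 (-2.97), the stress-induced gene Nupr1 (-2.95) and the transcription factor gene Atf5 (-2.86). They were followed by the cationic amino acid transporter gene Slc7a3 (-2.58), the cystine transporter gene Slc7a11 (-2.52), the ATP-gated channel gene P2rx3 (-2.45), the cystathionine gamma-lyase gene Cth (-2.26) and the mitochondrial folate enzyme gene Aldh1l2 (-2.13). For each of these 20 genes the 4 DS38 libraries all lay on one side of the 4 DMSO libraries, as the rule that chose them required. Passing the threshold was required too, so neither is further evidence for these genes. Their edgeR adjusted p-values ran up to 3.58e-06 for Trim66. Of all changed genes, 47.5% were raised, against 64.3% when libraries were scaled by their totals alone. Without both libraries numbered 1, a setting chosen after seeing the data, 5160 genes changed.

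Genes that report Hedgehog pathway activity were lower with the compound. Hhip, which encodes a Hedgehog-binding protein and is itself induced by the pathway, fell 2.81-fold, from 122 ± 7.83 to 43.5 ± 3.06 CPM (SD, n = 4 each; log2 fold change -1.49 ± 0.056 SE, edgeR adjusted p = 9.11e-13). Gli1, the transcription factor gene most used as a readout of the pathway, fell from 137 ± 3.54 to 90.9 ± 3.60 CPM (log2 fold change -0.60 ± 0.041 SE, edgeR adjusted p = 2.65e-09). Of 9 Hedgehog target genes tested, 7 fell, 0 rose and 2 did not pass the test, and 7 fell when adjusted over the list alone. The list was lower than other genes in camera (median log2 fold change -0.36, adjusted p = 3.49e-05; adjusted p = 0.0457 with an estimated correlation).

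Ptch1 fell from 256 ± 13.6 to 174 ± 17.4 CPM, with a log2 fold change of -0.56 (edgeR adjusted p = 2.44e-05). The counts do not separate mutant from intact Ptch1 transcripts. The cyclin D1 gene Ccnd1 had a log2 fold change of -0.38 (edgeR adjusted p = 5.50e-07). Mycn, another pathway target, stood at 56.7 ± 1.68 and 53.8 ± 2.31 CPM, a log2 difference of -0.08 ± 0.045 SE that did not pass the test (edgeR adjusted p = 0.186). Gli2, the main activator of the pathway, rose by 0.13 on the log2 scale (edgeR adjusted p = 0.0266), a call lost without DMSO replicate 2 (adjusted p = 0.107), DMSO replicate 3 (0.0691), DS38 replicate 1 (0.0677) or DS38 replicate 2 (0.0994), and after a correction for gene length and GC content (0.0908). Of 21 tested components of Hedgehog signal transduction, 5 rose, 3 fell and 13 did not pass, with the same counts of rises and falls when adjusted over the list alone. The co-receptor gene Gas1 fell (log2 fold change -0.69), as did the inhibitor gene Sufu (-0.19), whereas the co-receptor gene Boc (0.28) and the ligand-release gene Disp1 (0.44) rose. The list of components did not differ from other genes (camera adjusted p = 0.677).

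**Figure D1:**
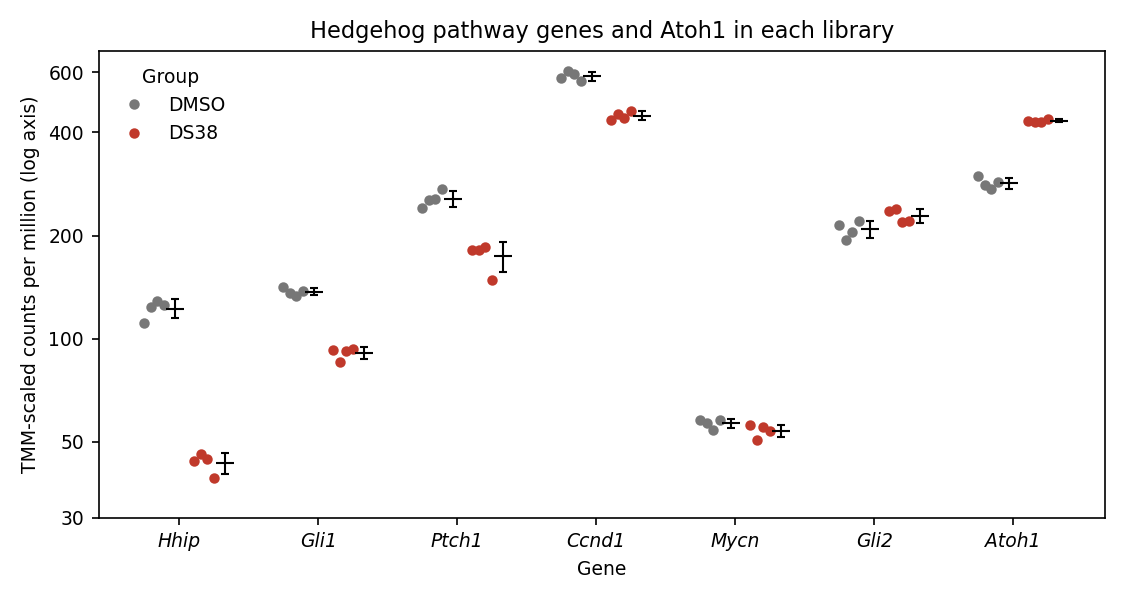
TMM-scaled CPM, on a log axis, for 7 genes in the 4 DMSO libraries (grey points) and the 4 DS38 libraries (red points), with the mean (horizontal mark) and SD (whiskers) of each group at their right. The points of Hhip, Gli1, Ptch1 and Ccnd1 lie lower in every DS38 library than in any DMSO library, those of Atoh1 lie higher, and those of Mycn and Gli2 overlap.

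Benzarone and its relatives are known inhibitors of the Eya phosphatases, so transcripts of the Eya family and of its partner families were examined. Eya3 was the best expressed Eya gene, at 88.4 ± 2.90 CPM in DMSO and 86.7 ± 1.59 in DS38, a log2 difference of -0.03 ± 0.040 SE that did not pass the test (edgeR adjusted p = 0.611). Eya4 stood near 1 CPM, at 0.898 ± 0.161 and 1.15 ± 0.279 (edgeR adjusted p = 0.238). Eya1 had 0 counts in all 8 libraries, which allows up to 0.175 CPM in the shallowest one, counting error only. Eya2 (17 counts over the 8 libraries) and Six4 (56 counts) fell under the filter on low counts. Six4 had 14 counts in DMSO and 42 in DS38, at 0.16 ± 0.0531 and 0.481 ± 0.0389 CPM of the plain library totals, higher in each DS38 library than in any DMSO library. Without the filter it passed in edgeR (log2 fold change 1.49, adjusted p = 0.0161) and in DESeq2 (adjusted p = 0.0388), and Eya2 did not pass in edgeR (adjusted p = 0.872). Genes close to silence had more counts in DS38 in general, as described below, and whether the rise of Six4 belongs to that pattern was not tested. Of 6 family members kept by the filter, 1 rose, 0 fell and 5 did not pass, the same when adjusted over the list alone. The riser was Dach1, a transcriptional co-regulator gene (log2 fold change 0.68, edgeR adjusted p = 1.52e-06), and the list itself was not called (camera adjusted p = 0.66).

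Genes induced by amino acid starvation through the transcription factor Atf4 fell almost as a block. Asns, which encodes asparagine synthetase, fell from 541 ± 13.4 to 227 ± 9.71 CPM (log2 fold change -1.252 ± 0.041 SE, edgeR adjusted p = 6.92e-14). Pck2, the mitochondrial phosphoenolpyruvate carboxykinase gene, had a log2 fold change of -1.23 (edgeR adjusted p = 1.35e-13), and Trib3 and Chac1 belong to the same list. Of 26 members tested, 24 fell, 1 rose and 1 did not pass, again 24 and 1 when adjusted over the list alone. The riser was Wars, a tryptophanyl-tRNA synthetase gene, at 0.14 on the log2 scale. The median log2 fold change was -1.22, with a camera adjusted p = 2.06e-25, and adjusted p = 0.0711 with an estimated correlation. Chaperones of the endoplasmic reticulum, a neighbouring stress response, did not move as a list. Of 18 tested, 4 rose, 2 fell and 12 did not pass, with the same rises and falls adjusted over the list alone (camera adjusted p = 0.733). Hspa5, the main chaperone gene of that compartment, rose by 0.23 on the log2 scale, while Herpud1, which serves protein degradation there, had a log2 fold change of -0.91. The median of this list was 0.03, its mean was -0.03 and camera's direction was up.

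**Figure D2:**
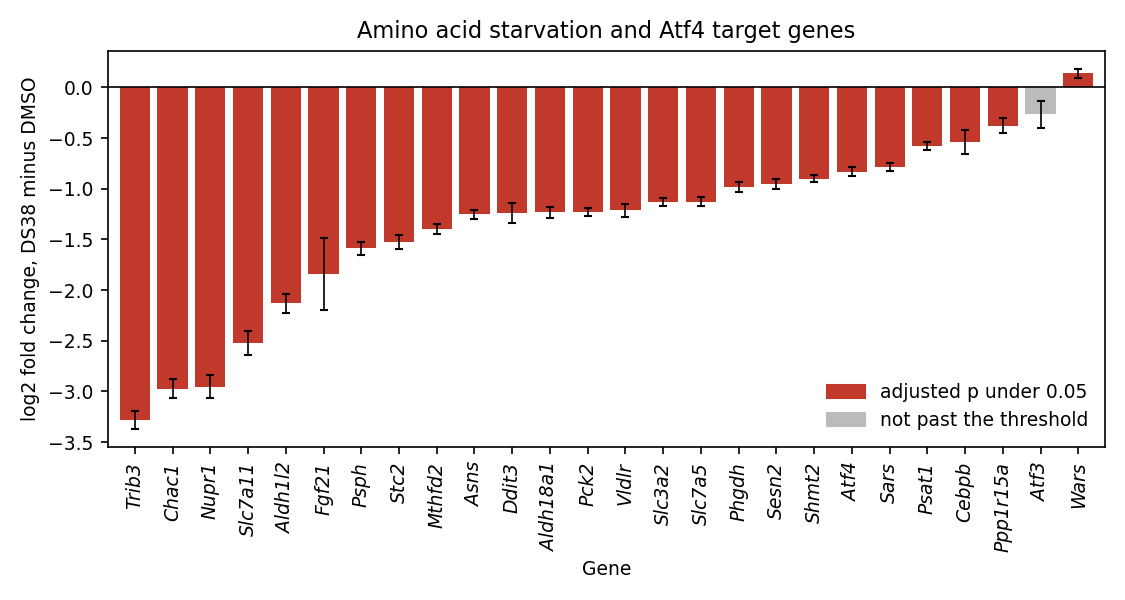
Log2 fold change, DS38 minus DMSO, of the 26 tested genes on the amino acid starvation and Atf4 list, with bars from 0 and whiskers of 1 standard error. Red bars passed edgeR's test at an adjusted p under 0.05, with 24 below 0 and Wars above it, and the grey bar of Atf3 did not pass.

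DNA replication genes fell, whereas mitosis genes moved in both directions. Rrm2, a subunit gene of ribonucleotide reductase, fell from 198 ± 11.6 to 114 ± 4.197 CPM (log2 fold change -0.79 ± 0.045 SE, edgeR adjusted p = 2.09e-10). The replication helicase gene Cdc45 (log2 fold change -0.76), the cyclin E2 gene Ccne2 (-0.71) and the sliding clamp gene Pcna (-0.64) fell as well. Of 30 DNA replication and G1/S genes tested, 26 fell, 0 rose and 4 did not pass, and 28 fell when adjusted over the list alone (median log2 fold change -0.36, camera adjusted p = 2.39e-15; adjusted p = 0.213 with an estimated correlation). Of 30 G2/M and mitosis genes, 13 rose, 7 fell and 10 did not pass, against 14 and 7 when adjusted over the list alone. The kinetochore motor gene Cenpe (log2 fold change 0.43), the centromere histone gene Cenpa (0.38) and the spindle gene Tpx2 (0.29) rose, and Cdk1, the mitotic kinase gene, fell (-0.33). That list was not called (camera adjusted p = 0.0579), though it was called after a correction for gene length and GC content (adjusted p = 0.0386) and in other settings.

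DNA damage response and repair genes fell with them. Of 22 tested, 16 fell, 1 rose and 5 did not pass, the same when adjusted over the list alone (median log2 fold change -0.21, camera adjusted p = 3.51e-05; adjusted p = 0.213 with an estimated correlation). Rad51ap1, a homologous recombination gene (log2 fold change -0.62), the checkpoint kinase gene Chek1 (-0.57) and Mdc1 (-0.36) fell, and Trp53bp1, a break-response gene, rose (0.40). Targets of p53 split, with 6 rises, 7 falls and 10 of 23 not passing, the same when adjusted over the list alone (camera adjusted p = 0.732). Cdkn1a, the p21 gene, fell (log2 fold change -0.71), as did Eda2r (-0.94) and Sesn2 (-0.96), which is also an Atf4 list member, while Trp53inp1 rose (0.71). Of 21 apoptosis regulators, 6 rose and 8 fell, or 7 and 9 when adjusted over the list alone, and 7 did not pass (camera adjusted p = 0.732). The pro-death genes Bbc3 (log2 fold change -0.61) and Hrk (-0.30) fell, as did the pro-survival gene Bcl2l2 (-0.37), and the pro-death gene Bcl2l11 rose (0.31).

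Neuronal differentiation genes were higher with DS-1-38. Cntn2, an axonal adhesion molecule gene, rose from 124 ± 8.10 to 231 ± 4.56 CPM (log2 fold change 0.90 ± 0.045 SE, edgeR adjusted p = 2.81e-11). The transcription factor gene Neurod2 (log2 fold change 0.67), the synaptic organiser gene Cbln1 (0.50) and the migration gene Dcx (0.40) rose as well. Of 23 members tested, 12 rose, 2 fell and 9 did not pass, against 15 and 3 when adjusted over the list alone. The list was called by camera (median log2 fold change 0.27, adjusted p = 9.05e-05; adjusted p = 0.0457 with an estimated correlation).

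Granule neuron progenitor genes, which mark the cell of origin of this tumour, did not move as a list. Atoh1, the transcription factor gene that defines these progenitors, rose from 284 ± 10.6 to 432 ± 4.54 CPM (log2 fold change 0.60 ± 0.039 SE, edgeR adjusted p = 9.09e-10). Barhl1 (log2 fold change 0.71) and Meis1 (0.55) rose too, and Nhlh2 fell (-0.33), all of them transcription factor genes. Of 12 tested, 5 rose, 2 fell and 5 did not pass, the same rises and falls when adjusted over the list alone (camera adjusted p = 0.296). Of 13 neural stem cell genes, 3 rose, 4 fell and 6 did not pass, with 3 and 5 when adjusted over the list alone (camera adjusted p = 0.732). The intermediate filament gene Vim rose (log2 fold change 0.88), Prom1 rose (0.20), and the transcription factor genes Sox2 (-0.53) and Sox9 (-0.41) fell.

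**Figure D3:**
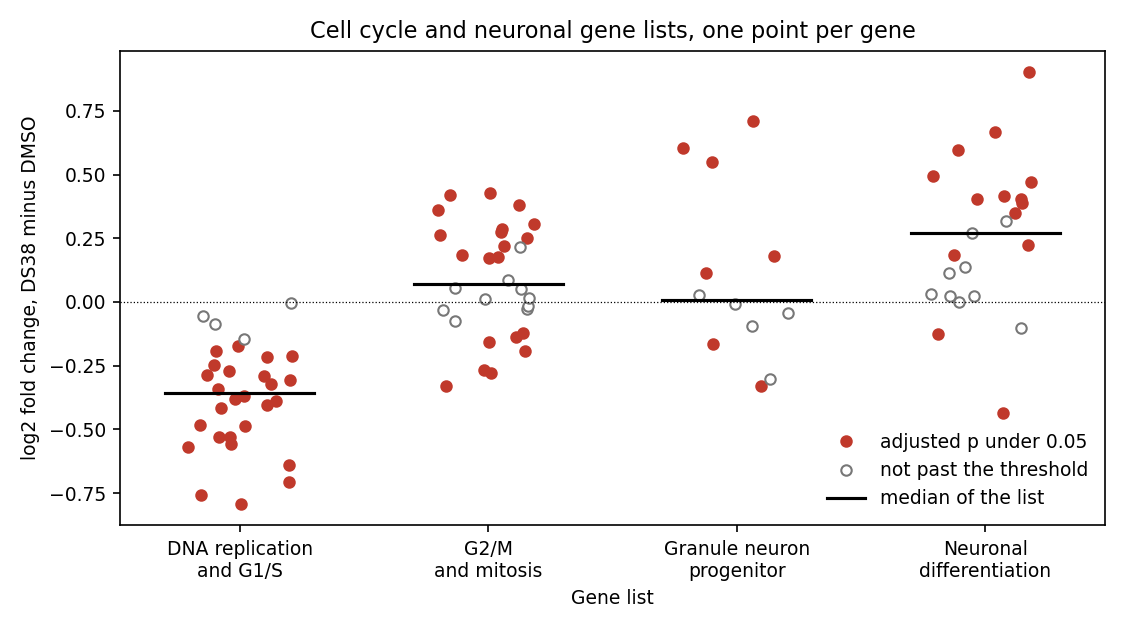
Log2 fold change, DS38 minus DMSO, with 1 point per tested gene of 4 lists, red where edgeR's adjusted p was under 0.05 and open where it was not, and a black line at each list's median. The medians are -0.36 for DNA replication and G1/S, 0.07 for G2/M and mitosis, 0.01 for granule neuron progenitor and 0.27 for neuronal differentiation genes.

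Many glycolysis and hypoxia genes fell, as did a part of the nuclear genes for oxidative phosphorylation, whereas some mitochondrially encoded genes rose. Ldha, which encodes lactate dehydrogenase A, fell from 1957 ± 164 to 1209 ± 95.2 CPM (log2 fold change -0.69 ± 0.065 SE, edgeR adjusted p = 1.18e-06). The oxidoreductase gene Ero1l (log2 fold change -0.78) and the glycolytic enzyme genes Pgam1 (-0.33) and Pkm (-0.30) fell too. Of 28 members tested, 16 fell, 1 rose and 11 did not pass, the same when adjusted over the list alone (median log2 fold change -0.32, camera adjusted p = 3.49e-05; adjusted p = 0.689 with an estimated correlation).

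Nuclear oxidative phosphorylation genes fell in 15 of 33 cases and rose in 0, 18 did not pass, and 15 fell when adjusted over the list alone. Atp5b (log2 fold change -0.34), Sdhd (-0.27), Sdha (-0.25) and Ndufa9 (-0.24), which encode subunits of the ATP synthase and of complexes of the chain, were among them. The list's median log2 fold change was -0.13 (camera adjusted p = 0.00391; adjusted p = 0.726 with an estimated correlation). Its call was lost without both libraries numbered 1 (adjusted p = 0.0864) and after a correction for gene length and GC content (adjusted p = 0.214), and across all genes the log2 fold change was higher in longer genes (Spearman's rho 0.223 across genes, which are not independent replicates).

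Of 13 mitochondrially encoded genes, 6 rose, 0 fell and 7 did not pass, with 6 rises when adjusted over the list alone (median log2 fold change 0.33, camera adjusted p = 0.0016; adjusted p = 0.689 with an estimated correlation). Examples were mt-Nd4 (log2 fold change 0.52), mt-Nd2 (0.51), mt-Cytb (0.43) and mt-Nd1 (0.43), which encode respiratory chain subunits. Mean values in DMSO ran from 6.69 to 3036 CPM over the 13 genes, and most of those that did not pass were among the lowest. The treatment of reads that match several places is not known, so the low values are uncertain. Mitochondrially encoded transcripts made up 0.79% to 1.04% of counts in the DMSO libraries and 1.17% to 1.36% in the DS38 libraries, a share that is also read as a sign of RNA or cell quality.

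A part of the lysosome and autophagy genes rose. Of 23 tested, 12 rose, 1 fell and 10 did not pass, the same when adjusted over the list alone (median log2 fold change 0.11, camera adjusted p = 0.00391; adjusted p = 0.371 with an estimated correlation). The autophagy receptor gene Sqstm1 (log2 fold change 0.40) and the saposin precursor gene Psap (0.28) rose, and Hexa, a hexosaminidase subunit gene, fell (-0.56). Lipid pathways were not called. Cholesterol genes split into 5 rises and 5 falls with 13 of 23 not passing, the same when adjusted over the list alone (camera adjusted p = 0.906, direction up, with a median of -0.00352). Examples were the sterol enzyme gene Cyp51 (log2 fold change -0.33) and the sterol transfer gene Stard4 (0.18). Of 15 fatty acid synthesis genes, 3 rose, 2 fell and 10 did not pass, the same when adjusted over the list alone (camera adjusted p = 0.906). They included Srebf1, a lipogenic transcription factor gene (log2 fold change 0.41), the fatty acid synthase gene Fasn (0.34) and Mid1ip1 (-0.66). Of 16 PPAR target genes, 4 rose, 3 fell and 9 did not pass, with 6 and 3 when adjusted over the list alone (camera adjusted p = 0.528). The carnitine transferase gene Cpt1a rose (log2 fold change 0.49), and the thioesterase gene Acot2 fell (-0.66).

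Feedback genes of MAPK signalling mostly fell and Notch genes mostly rose. Of 20 MAPK feedback and immediate early genes, 11 fell, 2 rose and 7 did not pass, with 12 and 2 when adjusted over the list alone (median log2 fold change -0.23, camera adjusted p = 0.0185; adjusted p = 0.26 with an estimated correlation). The feedback inhibitor genes Spry4 (log2 fold change -0.88) and Dusp6 (-0.65) and the immediate early gene Ier2 (-0.70) fell, whereas the phosphatase gene Dusp5 rose (0.43). Hey1, a Notch-induced repressor gene, rose from 43.6 ± 4.26 to 99.6 ± 4.96 CPM (log2 fold change 1.19 ± 0.060 SE, edgeR adjusted p = 1.82e-10). The list of Notch target genes also held pathway ligands and receptors, which made up all of its rises other than that of Hey1. Of the ligand genes, Dll1 (log2 fold change 1.00), Dll3 (0.36) and Jag1 (0.29) rose. The list is therefore not read as a measure of Notch target output. Of its 9 tested members, 5 rose, 1 fell and 3 did not pass, the same when adjusted over the list alone (median log2 fold change 0.36, camera adjusted p = 0.0128; adjusted p = 0.371 with an estimated correlation). The member that fell was Hes1, a repressor gene induced by Notch, at -0.32 on the log2 scale.

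Of 11 Wnt target genes, 0 rose, 2 fell and 9 did not pass, the same rises and falls when adjusted over the list alone (camera adjusted p = 0.791, direction down, with a median of 0.06). Wif1, a secreted Wnt inhibitor gene, was 1 of the 2 (log2 fold change -0.53). Of 19 Nrf2 targets, 8 rose, 3 fell and 8 did not pass, the same when adjusted over the list alone (camera adjusted p = 0.439). The pentose phosphate gene Pgd rose (log2 fold change 0.35), as did the malic enzyme gene Me1 (0.40), and the glutathione reductase gene Gsr fell (-0.23), along with Slc7a11, which is shared with the Atf4 list. The median of this list was 0.05, its mean -0.04 and camera's direction up. Of 14 interferon-stimulated genes, 1 rose, 3 fell and 10 did not pass, the same when adjusted over the list alone (camera adjusted p = 0.617). Rsad2, an antiviral enzyme gene, fell (log2 fold change -0.73). Of 3 genes of the aryl hydrocarbon receptor list tested, 0 passed in edgeR and 1 had an unadjusted p under 0.05, 0 passed when adjusted over the list alone, and they were too few for a list test. That gene, the receptor gene Ahr, stood at 0.296 ± 0.161 and 0.541 ± 0.133 CPM (edgeR adjusted p = 0.0621), and passed in limma-voom (adjusted p = 0.048) but not in DESeq2 (adjusted p = 0.189).

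Markers of other brain and stromal cells were examined because such cells could be mixed with the tumour line. Of 9 astrocyte markers, 2 rose, 4 fell and 3 did not pass, the same when adjusted over the list alone (camera adjusted p = 0.637). Gfap, an astrocyte filament gene, rose from 1.83 ± 0.521 to 3.07 ± 0.223 CPM (edgeR adjusted p = 0.00421), while the more abundant Sparcl1 fell (log2 fold change -0.27). Of 7 oligodendrocyte lineage markers, 2 fell, 0 rose and 5 did not pass, the same when adjusted over the list alone (camera adjusted p = 0.487). Pdgfra, the receptor gene of oligodendrocyte precursors, fell from 73.3 ± 1.87 to 51.1 ± 1.52 CPM (edgeR adjusted p = 2.44e-08). Olig2, on the same list, stood at 3.02 ± 0.567 and 2.56 ± 0.479 CPM and did not pass (edgeR adjusted p = 0.322). The fall of Pdgfra is therefore not read as a change in the number of such cells.

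Stromal, vascular and immune markers were mostly too low to test. Genes close to silence had more counts in DS38 in general, as described below. Whether the rises of weakly expressed markers belong to that pattern was not tested. Of 4 fibroblast and mural cell markers, 2 rose, and 4 when adjusted over the list alone. These were the collagen gene Col1a1, from 0.233 ± 0.130 to 0.798 ± 0.258 CPM (edgeR adjusted p = 0.0016), and the fibronectin gene Fn1, from 14.2 ± 2.698 to 23.6 ± 3.33 (edgeR adjusted p = 0.00235). Of 2 endothelial markers, Tek, a vascular receptor gene, passed at 0.318 ± 0.336 and 0.747 ± 0.104 CPM (edgeR adjusted p = 0.0295), a call lost without DMSO replicate 1 (adjusted p = 0.0857), DMSO replicate 2 (0.0939), DMSO replicate 4 (0.0766), DS38 replicate 2 (0.0935) or DS38 replicate 3 (0.0523). Cdh5, the other, did not pass (adjusted p = 0.816), and 1 of the 2 passed when adjusted over the list alone. The only microglia marker tested, Cd68, did not pass over all genes (edgeR adjusted p = 0.0854) but passed when adjusted over the list alone, where, as the single member, it keeps its unadjusted p, and stood at 1.17 ± 0.298 and 1.65 ± 0.190 CPM.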

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

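The check for single libraries that lie far from the rest of their group was set beforehand, and no test in this part was chosen after its result was seen. Among 296 sets of 4 values, each a named gene or a library measure in 1 group, 18 had an extreme library whose gap to its nearest neighbour exceeded Dixon's 95% critical value as a share of the group's range, where chance gives about 5% of sets. The extreme library was DS38 replicate 4 for Ptch1 (gap 0.906 of the range), Chrnb4 (0.941), Lmo7 (0.924) and Pkm (0.888), the lowest each time. In DS38 replicate 1, Nupr1 (gap 0.904) and Ccne2 (0.884) were lowest and Dusp5 (0.836) and Spry4 (0.836) highest. In DS38 replicate 2, Gli1 (gap 0.853) and Acot2 (0.933) were lowest, and in DS38 replicate 3, Vim (0.921) and Sqstm1 (0.959). Ahr, the aryl hydrocarbon receptor gene, at under 1 CPM, was also lowest in DS38 replicate 3 (gap 0.839). In DMSO replicate 1, Chrnb4 (gap 0.89) was lowest and Srebf1 (0.866) and Prom1 (0.858) highest, Hadha (0.839) was highest in DMSO replicate 3, and Dusp6 (0.847) lowest in DMSO replicate 4.

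Gli1 stood at 6.42 log2 CPM in DS38 replicate 2, against 6.53 in the next library. The gap of Ptch1 was wider, with 7.21 in DS38 replicate 4 and 7.502 in the next, and that of Chrnb4 was 3.78 against 4.14. All of the DS38 libraries of Gli1, Ptch1 and Chrnb4 still lay on one side of the DMSO libraries, which for Chrnb4 was a condition of being named.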

How the results depend on the processing

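The length and GC correction and the fit without both libraries numbered 1 were chosen after seeing the data. The number of changed genes, 5980, ranged from 5321 with DESeq2 to 6329 with the length and GC correction over the settings that kept every library, and every gene shared with a setting's calls had the same direction in both. Leaving out 1 library gave 4939 to 5912 changed genes, 214 to 352 raised and 111 to 143 lowered at least 2-fold, and 11 to 12 lists. The genes raised at least 2-fold numbered 530 without a filter and 58 under the stricter one, against 241, and the genes lowered at least 2-fold 63 under the stricter one, against 114. The stricter setting tested fewer low-count genes and turned the balance of rises and falls. After thinning to the smallest total, genes raised at least 2-fold numbered 198 and genes lowered at least 2-fold 111. Camera with an estimated correlation called 2 lists and fry, which asks another question, 19, against 11.

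The replicate numbers did not pair the libraries as a whole. Correlations of same-numbered libraries' deviations from their group means were 0.33, -0.07, 0.067 and -0.082, and not every library correlated best with its own number. The value of 0.33, for the libraries numbered 1, was the highest of any DMSO and DS38 pair, so a factor shared by that pair cannot be excluded. With the number as a block, 5594 genes changed, 2546 up and 3048 down, Gli2 was no longer called (edgeR adjusted p = 0.0555), and no other named gene's or list's call changed.

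Direction turned for results that passed no threshold in either setting, and the cause was not tested. Eya3 had a log2 difference of 0.03298 with library totals alone and 0.0004232 after thinning. Cdh5 stood at -0.24 without both libraries numbered 1, and between -0.13 and 0.21 with 1 library left out, below 0 without DMSO replicate 1 or DS38 replicate 1. Cyp1b1 stood between -0.0779 and 0.33 with 1 library left out, below 0 without DMSO replicate 2. For lists, whose direction is camera's, the medians were as follows. Fatty acid synthesis genes had 0.00443 with library totals alone, -0.0406 under the stricter filter, -0.0545 without both libraries numbered 1, and -0.0681 to -0.00951 with 1 library left out, turned without DMSO replicate 1 (-0.0286), DMSO replicate 4 (-0.0401) or DS38 replicate 2 (-0.00951). Replication-dependent histone genes had -0.00353 with library totals alone, and Hedgehog signal transduction components 0.0365 after the length and GC correction. Endoplasmic reticulum chaperones had 0.0192 without a filter and 0.0305 in fry. Cholesterol synthesis and uptake genes had -0.0123 without a filter, -0.00352 in fry, and -0.0218 to 0.0378 with 1 library left out, turned without DS38 replicate 4 (-0.0193).

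Of 143 named genes, 137 kept call and direction with the length and GC correction, 134 with library totals alone and 142 with DESeq2, and 132 of 141 did without both libraries numbered 1. Among the calls lost in 1 or more of these were those of Dnajb9, Isg15, Cnp and Tek.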

Other observations

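The tests of scaling, of denser vehicle cultures and of sequencing depth, the synthetase sets, the length and GC correction and the ribosomal protein counts were chosen only after the results they bear on were seen. Of 20 tested cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs for translation, 14 fell and 3 rose at an edgeR adjusted p under 0.05, with a median log2 fold change of -0.467. Of 17 mitochondrial synthetase genes, 3 fell and 2 rose, with a median of -0.00964. Cytosolic ribosomal protein genes fell in 60 of 84 cases and rose in 0, with a median log2 fold change of -0.249, or -0.191 after the length and GC correction. Mitochondrial ribosomal protein genes fell in 34 of 76 cases and rose in 5 (median -0.125). With library totals alone these medians were -0.406 for cytosolic synthetases, 0.0509 for mitochondrial ones, -0.189 for cytosolic and -0.0647 for mitochondrial ribosomal protein genes, while the median of all genes moved from -0.00932 to 0.0514, so the mitochondrial synthetase value follows that common shift. The hypothesis that cytosolic synthetase genes fell more than mitochondrial ones was tested by their difference in medians, which was -0.457 (permutation test over genes, two-sided, 100000 draws, p = 0.0056), although genes are not independent replicates. Several cytosolic synthetase genes are Atf4 targets, so this difference may belong to the fall of the Atf4 list.

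Counts of histone genes of the replication-dependent class split. Of 25 tested, 5 rose, 3 fell and 17 did not pass, or 5 and 2 when adjusted over the list alone (camera adjusted p = 0.703, median log2 fold change -0.06 with camera's direction up). The linker histone gene Hist1h1c rose from 11.8 ± 1.34 to 27.4 ± 1.58 CPM (SD, n = 4; edgeR adjusted p = 9.88e-10) and Hist1h2bc from 13.1 ± 1.76 to 30.4 ± 1.85 (edgeR adjusted p = 3.22e-09). These genes have many near-identical copies that can share reads. How well the mRNA kit captures their transcripts was not tested, so the split is not read as a change in histone expression.

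The 5980 changed genes were set against the other ways to split these 8 libraries, to see whether chance in the grouping could give as many. Among the 35 splits of the 8 libraries into 4 and 4, 1 gave as many, the real one, and the highest of the others gave 0 with edgeR and 0 with limma-voom. At an unadjusted p under 0.05 the other splits gave 45 to 2432 genes, against 7188 in the real one. The real grouping thus gave the most genes of the 35. Splits that mix the groups carry the group difference as spread, which pushes their counts down, so they do not by themselves exclude chance. None of them bears on a difference between cultures if libraries of a group shared one.

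The fall of the amino acid starvation and Atf4 list (median log2 fold change -1.22) was set against 3 technical explanations. Under the other 2 scalings its median was at most -1.16, and after the length and GC correction it was -1.2, which argues against both as the whole cause. Vehicle cultures that had grown denser could have used up more of their medium, which would raise these genes in DMSO. The glycolysis and hypoxia list was also lower with DS-1-38, with a median of -0.321, but its call was lost with an estimated correlation (adjusted p = 0.689), and culture density was not among the measurements used here, so this explanation and an effect of the compound cannot be told apart. The Atf4 transcript, itself a list member, fell from 325 ± 18.0 to 183 ± 3.97 CPM (SD, n = 4 each). Its log2 fold change was -0.83 (edgeR adjusted p = 4.53e-11). Whether the compound acts on amino acid supply or on Atf4 itself stays open and untested.

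Genes close to silence had more counts in DS38. With every library thinned to one total, 21725 ± 305 genes had a count in DMSO and 23237 ± 296 in DS38 (SD, n = 4), and the lowest DS38 library exceeded the highest DMSO library by 832 genes, more than the largest range within a group, 702, which argues against sequencing depth. If genomic DNA were the source, olfactory receptor genes and other near-silent coding genes would gain alike per kilobase. Instead the gain of 6349 other near-silent genes was 7.02 times that of 1117 olfactory receptor genes (95% bootstrap interval over genes 4.93 to 11.5), with summed CPM going from 31.5 ± 1.54 to 63.8 ± 5.85 and from 0.885 ± 0.394 to 1.88 ± 0.253 (exact permutation p = 0.0286 each, two-sided, the smallest this design allows). Summed CPM rose by a similar proportion in both sets, so the ratio largely follows the higher starting level of the other genes. The treatment of reads that match several places, which could affect the sets unequally, is not known. The comparison therefore does not exclude genomic DNA. A broad low-level rise of transcription may be another candidate explanation, but intronic reads, which would bear on it, were not analysed here.

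Longer genes had higher fold changes (Spearman's rho 0.223 across genes). The median log2 fold change was -0.21 in the shortest eighth of genes, up to 1110 bases, and 0.06 in the longest, from 8838 bases. After each library's trend with length and GC content was removed, the DNA replication and G1/S list kept a median of -0.385, against -0.356 before, so the trend cannot be its whole cause. The nuclear oxidative phosphorylation list, whose genes are short (median 2147 bases), went from -0.13 to -0.0655 and its camera adjusted p from 0.00391 to 0.214, so its fall is consistent with the length trend. Whether that trend came from the RNA, the library preparation or the cells was not tested.

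ENSMUSG00000119584, the most counted identifier in every library except DS38 replicates 1 and 2, had no symbol in the annotation used and differed between libraries of one group. What it encodes was not established, so its share is not read as expression, and whether it is ribosomal RNA left over in library preparation was not tested. It took 1.87%, 1.6%, 1.91% and 2.34% of counts in DMSO replicates 1 to 4, and 0.351%, 0.556%, 1.91% and 1.47% in DS38 replicates 1 to 4. Malat1, a nuclear long noncoding RNA singled out after its values were seen, rose (log2 fold change 0.77, edgeR adjusted p = 0.017), and Neat1, another, stood at 0.17 without passing (edgeR adjusted p = 0.249).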
